A study of Mus musculus with 10 samples.

How the data were processed

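The series holds 10 Agilent arrays of mouse splenic cells, with 2 replicates at each of 5 times after Schistosoma japonicum infection. Per the labels' protocols, spleen cells were taken with anti-CD11b magnetic beads, and infected RNA was labelled with Cy5 and control RNA with Cy3 on every array, so no dye swap exists. The labels mention a purity measurement by flow cytometry and give no value for it. The control channel was a pool of uninfected mice and counts here as 1 control sample. The ratio against 0 is the test, which leaves out the spread of the control, and a dye effect of a gene is not separated from infection. Such an effect cancels between times if it is the same on every array.

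Per the file headers, the scanner images were read with Agilent Feature Extraction 9.1.3.1, which gave for each spot the mean intensity and the median local background intensity in both channels. The authors' deposited processed intensities were background-subtracted and dye-normalised within each array by the same software, per the file headers. Feature Extraction also gave a log10 ratio of Cy5 over Cy3, per the file headers. The deposited series values, taken here from a table made for this work, were on a log2 scale with Cy5 over Cy3. They equalled the log10 ratio turned to log2 within 5e-05 once 9 of 10 columns were realigned, because in the table as used here values missing for 2 to 33 features saturated in both channels had moved later values out of place. As given, these columns correlated with their arrays at r of 0.00883 to 0.784. Scale and direction were thereby settled, the centring was that of Feature Extraction, and the median of every column was 0.

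Each array held 15051 spots, of which 14515 were gene spots for 11402 probes. Median intensity was 257 to 316 in Cy3 and 799 to 1244 in Cy5. Between 69.7% and 75.1% of gene spots were well above background in Cy3 and 87.9% to 90.3% in Cy5. Saturated gene spots numbered 362 to 766 in Cy5 and 0 to 34 in Cy3. Per the file headers, observed log ratios of the spiked controls had a slope of 0.753 to 0.804 against the expected ones. The number of arrays limits the precision. Both arrays of 18 weeks lay on slide 2 and scan 2, and the other 8 on slide 1 and scan 1.

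The analysis used R 4.3.3, limma 3.58.1, statmod 1.5.0 and the package data.table in version 1.17.8. Background was corrected with normexp at an offset of 50 and log2 ratios were normalised by loess within each array, with control spots at weight 0. Outlier spots, 20 to 49 per array, were left out, saturated spots were kept, and spots of a probe were averaged. A probe was kept if it was well above background in at least 1 channel on both arrays of at least 1 time, which left 10542 probes. Of several probes of a gene the brightest was used, and 1528 genes had more than 1. Probes were named through a RefSeq table of assembly GRCm38.p6, 7176 by accession, 725 by a synonym and 2697 by a symbol that was current. A further 804 kept the name in the files. This gave 7569 genes tested of 7969 on the array, in which 15 pairs of names that differ only in letter case, 14 of them MHC genes, are counted apart. No gene list holds both names of a pair.

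One limma fit held all 10 arrays with a mean per time, with 5 residual and 2.22 prior degrees of freedom. Each time was tested against 0 and against the time before it, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and an F-test covered all times. The limma function camera tested gene lists with a preset correlation of 0.01, adjusted over 125 tests against the pool and 100 between times for 25 of 26 lists, as 1 list had too few measured members. It was repeated with an estimated correlation and with fry. The 26 lists cover macrophage activation and function, interferon, type 2 and matrix genes, metabolism, the cell cycle and the markers of cell types a bead selection of spleen could hold. Some genes, such as Cd8a, Ccr7 and Ccl5, are in more than 1 list, so list results are not independent. A gene not well above background or saturated on both arrays of a time has only a bound there. It is given as at least N-fold from the channel means after loess and Aquantile normalisation, which is open to dye bias. A gene saturated in the brighter channel that was called lower is given no fold.

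Groups, tests, lists, alternatives and genes to name were chosen before the data were examined, apart from those marked below as chosen later. The 4 later alternatives omitted saturated spots, took series values as given, joined names across letter case, or estimated correlation with the replicate block. The named genes are, at each time against the pool, the 8 largest rises and 8 largest falls past the threshold with the same sign on both arrays, and up to 3 passing members per list with the largest change, or up to 4 to illustrate a list with a call. Between times they are the 5 largest rises and 5 largest falls whose later arrays both lay on the same side of both earlier arrays. Symbols that only repeat an accession or clone were passed over. In addition 21 genes were fixed whatever their values, of which 8 were not measured by a matched probe and are not analysed here. The text prints a part of these genes.

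The labels number replicates 1 and 2 at every time. Over the 10 pairs of times the deviations of same-numbered arrays from their time's mean correlated at 0.101 to 0.692 (median 0.378), above 0.1 in 10 of 10, so the numbers were taken to pair the arrays, and they also match the position on the slide. A fit with the replicate number as a block was therefore set beside the results it changed. Alternatives covered background correction, normalisation, the filter on dim probes, the choice of probe, the variance prior, array weights, the slide, the deposited series values, a 2-fold minimum and leaving out each array. The fit and the list test were tested on simulated data for 7569 genes with known changes in 200 of them and a shift in the 12 genes of 1 list. Changes between 4.5 and 8 weeks were recovered there in 37.3%, 82.1% and 93.9% of cases at 1.5, 2 and 4-fold, with 13 false calls among 163, which include genes of that list. A list shifted there was called, with 0 calls among 24 other lists. The simulated noise was independent between genes.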

Results

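Gene expression was measured in CD11b-positive cells, called splenic macrophages in the labels, that were taken with magnetic beads from the spleens of male C57BL/6 mice infected with Schistosoma japonicum, a blood fluke whose eggs lodge in liver and gut. Each mouse received 35 cercariae, the larvae that enter through skin, at 8 weeks of age. Cells were collected 1, 4.5, 8, 12 or 18 weeks into infection, with 2 arrays per time. Age and time cannot be told apart. On every array the infected sample carried Cy5 and a pool of cells from uninfected mice carried Cy3. Values below are log2 ratios of infected cells to that pool, as the mean of 2 arrays ± the standard error of the limma fit (n = 2 at each time), for 7569 genes tested, or 7554 once names that differ only in letter case are joined. Replicate arrays correlated across genes with r of 0.596 at 1 week, 0.744 at 4.5 weeks, 0.944 at 8 weeks, 0.864 at 12 weeks and 0.883 at 18 weeks. The labels do not say whether the 2 samples of a time came from separate mice, so p-values measure only the spread between these samples, and the ratio against the pool leaves out the spread of the control itself.

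Fewer genes differed from the pool at 1 and 4.5 weeks than at 8 weeks and later. At 1 week 478 genes differed, 174 higher and 304 lower, and at 4.5 weeks 1318 did, 676 higher and 642 lower. At 8 weeks 3913 genes differed (2219 higher, 1694 lower), at 12 weeks 3687 (2029 higher, 1658 lower) and at 18 weeks 3893 (2004 higher, 1889 lower), each at an adjusted p under 0.05. Changes of at least 2-fold were fewer, with 6 genes higher and 58 lower at 1 week, 90 and 126 at 4.5 weeks, 359 and 566 at 8 weeks, 298 and 509 at 12 weeks, and 304 and 673 at 18 weeks. With the replicate block the counts were 784 at 1 week and 1995 at 4.5 weeks.

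Genes with saturated spots were part of the early counts. Of the genes lower at 1 week 135 (44.4%) had Cy5 saturated on both arrays, against 133 (20.7%) at 4.5 weeks, 140 (8.26%) at 8 weeks, 127 (7.66%) at 12 weeks and 85 (4.5%) at 18 weeks, and such genes are given no fold below. Without saturated spots the 1 week count was 187, with 93 higher and 94 lower. The early counts also moved with the normalisation. Median centring gave 1843 genes at 1 week (871 higher, 972 lower) and 2863 at 4.5 weeks, scaling between arrays gave 1975 (992 higher, 983 lower) and 2173, and array weights gave 747 at 1 week. Agilent's processed signals gave 135 higher and 516 lower genes at 1 week and 560 and 1030 at 4.5 weeks. Leaving out a replicate of the time itself lowered the counts at 1, 4.5 and 8 weeks, and most genes then left at 1 week were lower. Of the later counts 2155 were left without 12 weeks replicate 1 and 2490 without 18 weeks replicate 1. Without either array of 8 weeks the 1 week count was 272.

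**Figure D1:**
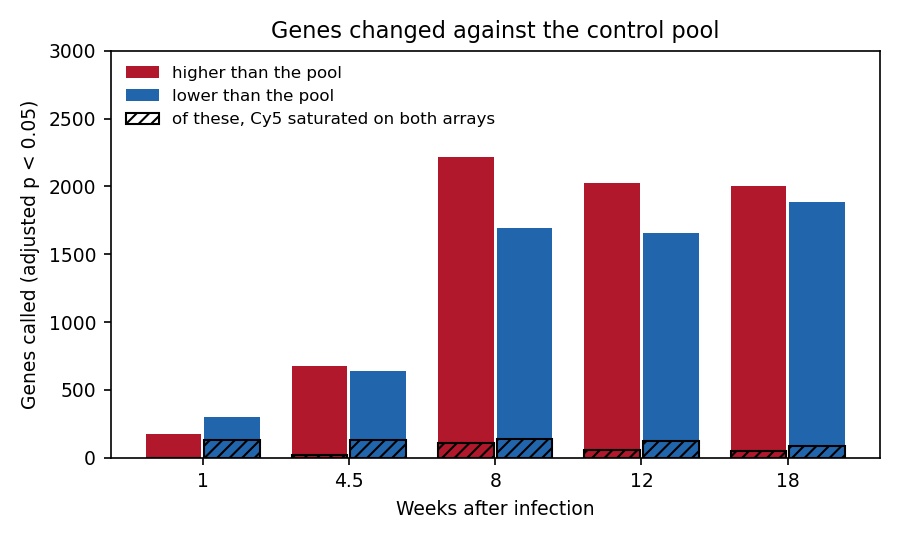
Genes with a log2 ratio to the control pool past an adjusted p of 0.05 (vertical axis, number of genes) at each time after infection (horizontal axis, weeks), higher in red and lower in blue, with hatching for genes whose Cy5 was saturated on both arrays. Higher genes number 174 at 1 week and 2219 at 8 weeks, and the hatched part of the lower genes is 135 of 304 at 1 week and 85 of 1889 at 18 weeks.

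At 1 week, before egg laying begins in this infection, the serum amyloid A genes Saa1 and Saa3 rose. Saa1 was 2.67 ± 0.31 and Saa3 2.49 ± 0.35 above the pool (adjusted p = 0.00479 and 0.0106). The 3 other Saa1 probes lay between 0.16 and 1.54. Neat1, a nuclear long noncoding RNA, rose by 1.39 ± 0.14, Ccr3, the eotaxin receptor of eosinophils, by 1.16 ± 0.19, and the lipid-sensing nuclear receptors Nr1h3 and Pparg by 0.68 and 0.63. Ifng, the gene of interferon gamma, stood at -1.62 ± 0.34, the neutrophil chemokine Cxcl2 at -2.83 ± 0.58, the kinase Plk3 at -1.59 ± 0.18 and the immediate early gene Egr1 at -1.42, all lower than the pool. Of 10 natural killer and cytotoxic markers tested, 4 fell (5 adjusted over the list alone), among them the receptors Klrb1c (-1.05), Il2rb (-1.10) and Ncr1 (-1.03). That list shifted down with an adjusted p of 4.61e-05, or 2.81e-05 without saturated spots, and with an adjusted p = 0.343 with an estimated correlation.

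The other list calls of 1 week rested in part on saturated spots. MHC class II presentation was lower with an adjusted p of 0.000211, or 0.325 with an estimated correlation (5 of 11 members lower, both over all genes and adjusted over the list alone), with Cy5 saturated in 4 of the 5, namely Cd74, H2-Ab1, H2-Eb1 and Ifi30. Without saturated spots the adjusted p was 0.268. Classical activation (M1) was lower with an adjusted p of 0.0106, or 0.28 with an estimated correlation (4 of 23 members, 7 adjusted over the list alone), with Cy5 saturated in 3 of the 4, and 0.174 without saturated spots. Neutrophil markers were lower with an adjusted p of 0.0389, or 0.28 with an estimated correlation (2 of 5 members, and 3 adjusted over the list alone beside 1 higher), or 0.0586 with the replicate block, and were not tested without saturated spots. Mpo, the granule enzyme myeloperoxidase, stood at -1.08 ± 0.19. Neutrophil markers lost the call without either array of 4.5 or 18 weeks (adjusted p up to 0.0565). Mpo lost the call without 1 week replicate 1 (adjusted p = 0.158). H2-Ab1 and H2-Eb1 lost the call without 1 week replicate 2 (adjusted p = 0.0906 and 0.104). Ifi30 lost the call without either array of 1, 4.5 or 8 weeks (adjusted p up to 0.308).

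Most of the named changes of 1 week depended on single arrays. Ccr3, Klrb1c and Pparg lost the call without either array of 1 week (adjusted p up to 0.207, 0.162 and 0.25). Cxcl2 and Ifng lost the call without either array of 1, 4.5 or 8 weeks (adjusted p up to 0.264 and 0.289). Egr1, Nr1h3, Plk3 and Saa3 lost the call without 1 week replicate 1 (adjusted p = 0.136, 0.152, 0.0901 and 0.0986). Il2rb and Ncr1 lost the call without either array of 1 or 8 weeks (adjusted p up to 0.271 and 0.26).

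At 4.5 weeks, when worms mature and eggs first appear, Rgs13 and Rassf6 were among the largest single-gene rises, and Vcam1 and Spic were among the largest falls. The cell cycle genes Cdc20 (2.60 ± 0.16) and Ccnb1 (2.50 ± 0.09), an activator of the anaphase-promoting complex and the mitotic cyclin B1, were up, as were the mitotic kinase Nek2 (2.26 ± 0.17) and Cdca3 (2.13 ± 0.19). The largest rises with a measured ratio were Rgs13, a regulator of G-protein signalling known from germinal centre B cells (3.33 ± 0.22), and Rassf6 (3.26 ± 0.24). Ackr4, a scavenging chemokine receptor, was at least 6.96-fold higher (adjusted p = 0.000418) with the pool not well above background. Ppbp, the platelet basic protein, rose by 2.45 ± 0.31 and Mzb1, a chaperone of antibody-secreting cells, by 1.44 ± 0.14. Among the largest falls were Vcam1 (-2.51 ± 0.31), an adhesion molecule of red pulp macrophages, Spic (-2.11 ± 0.22), the transcription factor that red pulp macrophages need, Cd14 (-2.18 ± 0.29), the co-receptor for lipopolysaccharide, Ccr3 (-2.15 ± 0.19) and the complement gene C2 (-2.04 ± 0.12).

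By list, 9 of 12 cell cycle genes rose at 4.5 weeks (10 adjusted over the list alone), with a median of 1.67 and an adjusted p of 4.38e-07 (0.28 with an estimated correlation). Of 13 T cell markers 9 rose (10 adjusted over the list alone), with Cd3g at 1.47 ± 0.25, Lat at 1.29 ± 0.26 and Cd3d at 1.22 ± 0.22 (list adjusted p = 0.000151, and 0.372 with an estimated correlation). Red pulp macrophage and iron genes fell in 5 of 7 (6 adjusted over the list alone, adjusted p = 0.000151, or 0.28 with an estimated correlation), with Blvra, a biliverdin reductase, at -0.78. Pattern recognition and scavenger receptors fell in 7 of 16 (10 adjusted over the list alone, adjusted p = 2.21e-06, or 0.253 with an estimated correlation), with the hyaluronan receptor Stab2 at -1.65 ± 0.08 and Tlr2 at -1.07. Classical activation genes fell in 9 of 23 (11 adjusted over the list alone, beside 1 higher, adjusted p = 0.000527, or 0.28 with an estimated correlation), with Il18 at -1.36 and Il1a at -0.99. Monocyte and macrophage identity genes fell in 6 of 14, 3 of them saturated in Cy5 (6 adjusted over the list alone, adjusted p = 0.0033, or 0.28 with an estimated correlation). Neutrophil markers fell in 3 of 5 (4 adjusted over the list alone, adjusted p = 0.00077, or 0.28 with an estimated correlation), with Cxcr2 at -1.28 and Fpr1 at -1.10. Without saturated spots 3 of these 5 were left, 1 of them lower, and the list was not tested.

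Further lists were lower at 4.5 weeks with all spots and did not pass without saturated spots. Complement and Fc receptors (7 of 19 lower and Fcgr2b higher, over all genes and adjusted over the list alone, adjusted p = 0.00692) lost the call without saturated spots (0.933), as did MHC class II (4 of 11, all 4 saturated, and 4 adjusted over the list alone, 0.0155 and 0.96). With an estimated correlation the adjusted p was 0.28 and 0.368. The call was also lost for alternative activation (M2, 3 of 12, and 3 adjusted over the list alone, 0.0316 and 0.0654), and lysosome and cathepsins (2 of 6, both saturated, and 2 adjusted over the list alone, 0.0421 and 0.275, or 0.0508 with the replicate block). For these 2 lists the adjusted p was 0.28 and 0.347 with an estimated correlation. MHC class II presentation lost the call without 4.5 weeks replicate 2 (adjusted p = 0.187). Alternative activation (M2), Cd14 and Cd3g lost the call without 4.5 weeks replicate 1 (adjusted p = 0.0797, 0.0519 and 0.11). Lysosome and cathepsins lost the call without either array of 8 weeks or 4.5 weeks replicate 2 (adjusted p up to 0.118). Blvra, Cd3d, Cxcr2, Il18, Il1a, Lat and Tlr2 lost the call without either array of 4.5 weeks (adjusted p up to 0.0736, 0.135, 0.133, 0.0666, 0.0873, 0.154 and 0.197).

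By 8 weeks, when granulomas form around eggs, the largest single-gene rises included Slc4a4, Ms4a3, Ctsg and Saa1, and the largest falls Spic and Vcam1. Ms4a3, a marker of granulocyte and monocyte progenitors, was at least 22.9-fold higher, the granule protease Ctsg at least 20.4-fold, the protease inhibitor Serpinb1c at least 14.1-fold and Mpo at least 8.95-fold, each with Cy5 saturated (adjusted p = 3.05e-05, 1.68e-05, 1.5e-05 and 3.04e-05). The sodium bicarbonate cotransporter Slc4a4 was at least 27.3-fold higher against a pool not well above background (adjusted p = 1.5e-05). Saa1 rose by 3.98 ± 0.31, Gp1bb, a subunit of the platelet receptor for von Willebrand factor, by 3.93 ± 0.26, Septin5 by 3.94 ± 0.27 and Ccnb1 by 3.86 ± 0.09. In the opposite direction Spic stood at -3.93 ± 0.22 and Vcam1 at -3.92 ± 0.31, with Sucnr1, the succinate receptor, at -3.79 ± 0.17, Rgs1 at -3.78 ± 0.17, the adrenergic receptor Adrb1 at -3.55 ± 0.25 and C2 at -3.36 ± 0.12.

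Markers of lymphocytes fell together at 8 weeks. B cell markers fell in 11 of 12 (11 adjusted over the list alone, median -1.88, adjusted p = 5.92e-06, or 0.328 with an estimated correlation), with Fcer2a at -2.31 ± 0.11 and Blk at -2.05 ± 0.24. T cell markers fell in 12 of 13 (12 adjusted over the list alone, median -1.46, adjusted p = 5.92e-06, or 0.351 with an estimated correlation), with Il7r at -2.16 ± 0.29 and Cd6 at -1.74 ± 0.22. NK markers fell in 8 of 10 (8 adjusted over the list alone, adjusted p = 0.000906, or 0.368 with an estimated correlation), with Klrb1c at -2.93 ± 0.16 and Ncr1 at -2.67 ± 0.20, while the granzyme gene Gzmk rose by 0.45. Members that ran against their list, such as Gzmk, were picked for naming here and below after their values were seen. Dendritic cell markers fell in 5 of 6 (5 adjusted over the list alone, adjusted p = 0.00254, or 0.28 with an estimated correlation), with Flt3 at -2.47 ± 0.17. All 6 megakaryocyte and platelet markers rose (6 adjusted over the list alone, median 2.04, adjusted p = 0.0051, or 0.347 with an estimated correlation), with Ppbp at 2.86 ± 0.31 and Treml1 at 2.44 ± 0.31. Of 12 cell cycle genes 10 rose (11 adjusted over the list alone, median 3.09, adjusted p = 4.15e-06, or 0.28 with an estimated correlation), with Ube2c at 3.65 ± 0.25. Neutrophil markers did not pass at 8 weeks (3 of 5 higher and 1 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.158, or 0.347 with an estimated correlation), with Fpr1, Ctsg and Mpo higher, Csf3r lower and a median of 1.17.

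All 11 MHC class II genes fell at 8 weeks (11 adjusted over the list alone), 3 of them saturated in Cy5. The adjusted p was 2.39e-07, or 0.28 with an estimated correlation. H2-Aa stood at -2.91 ± 0.18 and H2-DMb2 at -2.38 ± 0.22. Whether B cells account for this was not tested. Classical activation genes fell in 19 of 23 (21 adjusted over the list alone, adjusted p = 2.39e-07, or 0.253 with an estimated correlation), with the chemokine Ccl3 at -2.59 ± 0.29 and Il18 at -2.56 ± 0.20, and Tnf rose by 1.38 ± 0.17. Red pulp macrophage genes fell in 6 of 7 (6 adjusted over the list alone, adjusted p = 0.000416, or 0.28 with an estimated correlation). Pattern recognition receptors fell in 12 of 16 with Myd88 higher (12 and 1 adjusted over the list alone, adjusted p = 0.000142, or 0.257 with an estimated correlation). Interferon-stimulated genes fell in 8 of 25, with the guanylate-binding gene Gbp2b higher (8 and 1 adjusted over the list alone, adjusted p = 0.00813, or 0.583 with an estimated correlation). The test fry did not keep this list call. Ifit3 stood at -2.11 ± 0.28 and Mx2 at -2.06 ± 0.22.

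Monocyte and macrophage identity genes moved both ways at 8 weeks, as 9 of 14 fell and 3 rose (9 and 3 adjusted over the list alone, adjusted p = 0.0111, or 0.327 with an estimated correlation). Higher were Itgam, Spi1 and Csf2rb. The F4/80-related receptor gene Adgre4 stood at -2.90 ± 0.14 and the fractalkine receptor Cx3cr1 at -1.97 ± 0.15, while Itgam, the gene of CD11b itself, rose by 2.02 ± 0.25. Lysosome genes fell in 4 of 6 (4 adjusted over the list alone, adjusted p = 0.0176, or 0.328 with an estimated correlation). Complement and Fc receptors fell in 8 of 19 with C3, C3ar1, Itgam and Fcgr2b higher (8 and 4 adjusted over the list alone, adjusted p = 0.0459, or 0.347 with an estimated correlation and 0.0576 with the replicate block). Without saturated spots these 3 calls were lost, at an adjusted p of 0.095, 0.209 and 0.881. Complement and Fc receptors lost the call without either array of 18 weeks, 1 week replicate 2 or 8 weeks replicate 1 (adjusted p up to 0.0979). Interferon-stimulated genes lost the call without 8 weeks replicate 1 (adjusted p = 0.412).

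**Figure D2:**
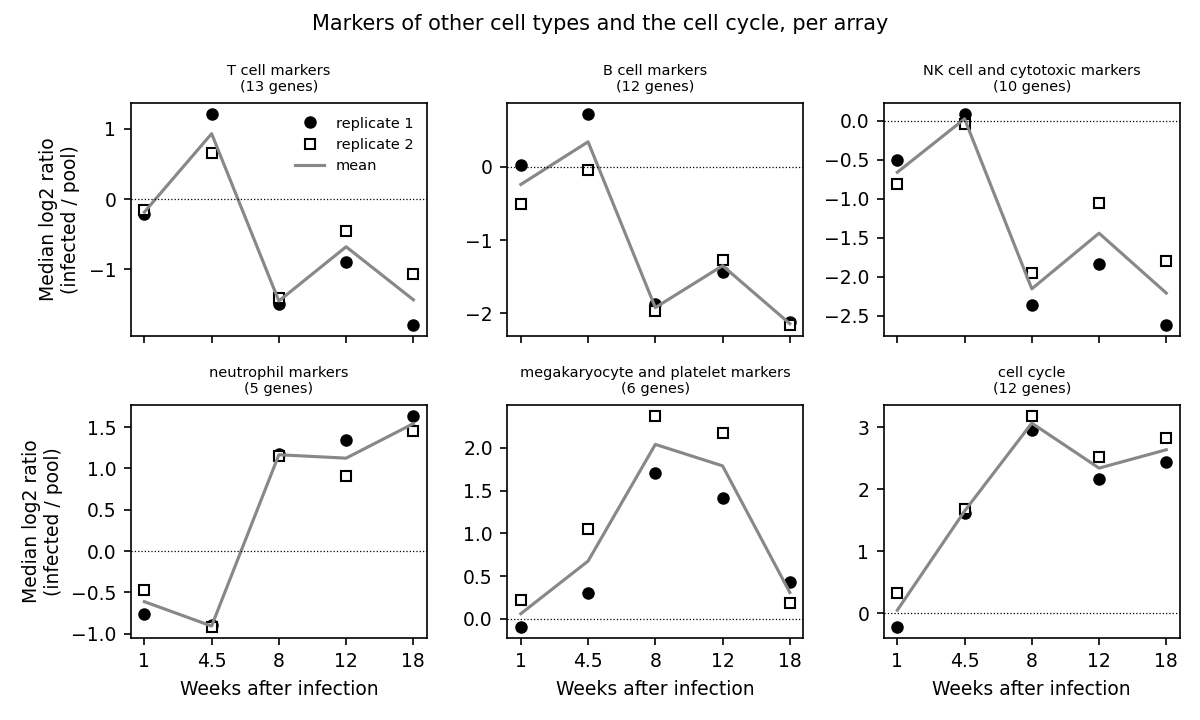
Median log2 ratio to the pool over the tested members of 6 gene lists (vertical axes) at each time (horizontal axes, weeks after infection), with a filled circle for replicate 1, an open square for replicate 2 and a line through their mean. At 8 weeks the T, B and NK cell medians lie at -1.40 or below on both arrays and the neutrophil and platelet medians at 1.16 or above.

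At 12 weeks the largest single-gene rises again included Slc4a4 and Ms4a3, and the largest falls Sucnr1 and Spic. Neutrophil markers, which include Ctsg and Mpo, did not pass at this time (4 higher and 1 lower of 5, 4 and 1 adjusted over the list alone, adjusted p = 0.102, or 0.328 with an estimated correlation). Slc4a4 was at least 28.9-fold and Ms4a3 at least 20.5-fold higher (adjusted p = 2.18e-05 and 5.01e-05), Gp1bb stood at 3.75 ± 0.26, Ctsg at 3.68 ± 0.20, Saa1 at 3.54 ± 0.31 and Orm1, the acute-phase protein orosomucoid, at 3.73 ± 0.22. Sucnr1 (-4.11 ± 0.17, with infected cells well above background on 1 of 2 arrays), Spic (-3.81 ± 0.22), Vcam1 (-3.36 ± 0.31), Adgrl3 (-3.38 ± 0.13), Rgs1 (-3.33 ± 0.17) and Ccnd1, the gene of cyclin D1 (-3.04 ± 0.17), were lower. All 11 MHC class II genes fell (11 adjusted over the list alone, 2 saturated in Cy5, adjusted p = 4.38e-07, or 0.28 with an estimated correlation). So did 15 of 23 classical activation genes with Tnf higher at 0.82 ± 0.17 (15 and 1 adjusted over the list alone, adjusted p = 4.15e-06, or 0.257 with an estimated correlation). Cell cycle genes rose in 10 of 12 (10 adjusted over the list alone, median 2.37, adjusted p = 5.92e-06, or 0.28 with an estimated correlation), with Cdc20 at 3.16 ± 0.16. Platelet markers rose in all 6 (6 adjusted over the list alone, adjusted p = 0.00513, or 0.347 with an estimated correlation).

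B cell markers fell in 10 of 12 at 12 weeks (10 adjusted over the list alone, adjusted p = 6.93e-05), T cell markers in 6 of 13 (7 adjusted over the list alone, adjusted p = 0.00359), NK markers in 8 of 10 with Gzmk higher (8 and 1 adjusted over the list alone, adjusted p = 0.00135) and dendritic cell markers in 5 of 6 (5 adjusted over the list alone, adjusted p = 0.00498). With an estimated correlation their adjusted p was 0.347, 0.487, 0.368 and 0.288 in this order. Examples were Cd79b (-1.59 ± 0.22, with Cy5 saturated on 1 of 2 arrays), Icos (-1.12 ± 0.16), Ncr1 (-2.74 ± 0.20) and Flt3 (-2.41 ± 0.17). Red pulp genes fell in 6 of 7 (6 adjusted over the list alone, adjusted p = 0.000773, or 0.28 with an estimated correlation). Pattern recognition receptors fell in 8 of 16 with Myd88 higher (8 and 1 adjusted over the list alone, adjusted p = 0.00153, or 0.28 with an estimated correlation). Lower with a call that ended without saturated spots were monocyte and macrophage identity (8 of 14 lower with Itgam and Spi1 higher, 8 and 3 adjusted over the list alone, adjusted p = 0.0121 and 0.174), lysosome genes (4 of 6, and 4 adjusted over the list alone, 0.0244 and 0.119), plasma cell markers (5 of 7, and 5 adjusted over the list alone, 0.0314 and 0.175, or 0.0759 with the replicate block) and complement and Fc receptors (7 of 19 lower with C3, C3ar1 and Itgam higher, 7 and 3 adjusted over the list alone, 0.0421 and 0.77, or 0.0566 with the replicate block). Their adjusted p with an estimated correlation was 0.328, 0.337, 0.33 and 0.343. Complement and Fc receptors lost the call without either array of 18 weeks (adjusted p up to 0.0651). Lysosome and cathepsins and Tnf lost the call without 12 weeks replicate 2 (adjusted p = 0.0683 and 0.0742).

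At 18 weeks Ms4a3 and Orm1 were among the largest single-gene rises and Sucnr1 and Slamf8 among the largest falls. Neutrophil markers, which include Ctsg and Mpo, did not pass at 18 weeks (3 higher and 1 lower of 5, 4 and 1 adjusted over the list alone, adjusted p = 0.0935, or 0.328 with an estimated correlation). Orm1 rose by 4.59 ± 0.22 and Orm2 by 4.15 ± 0.20, while Saa1 was at least 19.7-fold and Saa3 at least 15.6-fold higher with Cy5 saturated (adjusted p = 6.24e-05 and 0.000142). Ms4a3 stood at 4.66 ± 0.27, Ctsg at 4.28 ± 0.20 and Serpinb1c at 3.94 ± 0.14, all 3 with Cy5 saturated on 1 of the 2 arrays, and Slc4a4 was at least 20.5-fold higher (adjusted p = 1.33e-05). Sucnr1, whose probe was not well above background in infected cells (adjusted p = 8.15e-06), the immune receptor Slamf8 (-4.38 ± 0.63), Spic (-4.23 ± 0.22), the interferon-induced GTPase Gbp8 (-4.05 ± 0.41), Ccnd1 (-3.96 ± 0.17), Tnfrsf13c, the receptor for the B cell survival factor BAFF (-3.96 ± 0.25), and Vcam1 (-3.85 ± 0.31) were lower. The genes of chitinase-like proteins were higher with Cy5 saturated, Chil4 at least 8.45-fold and Chil3 at least 5.71-fold (adjusted p = 8.42e-05 and 1.91e-05). The alternative activation (M2) list that holds both did not pass at 18 weeks, with 4 of 12 higher and 4 lower (4 and 4 adjusted over the list alone), a median of 0.013 and an adjusted p of 0.883 (0.904 with an estimated correlation). At 8 weeks that list had an adjusted p of 0.213 with all spots and was lower without saturated spots (adjusted p = 0.0169).

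All 12 B cell markers and all 11 MHC class II genes fell at 18 weeks (12 and 11 adjusted over the list alone, 2 of the latter saturated in Cy5, adjusted p = 1.53e-06 and 2.5e-07, or 0.327 and 0.28 with an estimated correlation), with Ms4a1, the gene of CD20, at -3.45 ± 0.24 and H2-Aa at -2.93 ± 0.18. Interferon-stimulated genes fell in 19 of 25 (20 adjusted over the list alone, median -1.29, adjusted p = 2.69e-05, or 0.389 with an estimated correlation), with Iigp1 at -3.60 ± 0.81 and Gbp3 at -3.01 ± 0.67. T cell markers fell in 12 of 13 (12 adjusted over the list alone, adjusted p = 3.73e-05), NK markers in 8 of 10 with Gzmk higher (8 and 1 adjusted over the list alone, adjusted p = 0.000849), dendritic cell markers in 5 of 6 (5 adjusted over the list alone, adjusted p = 0.00345) and plasma cell markers in 5 of 7 (5 adjusted over the list alone, adjusted p = 0.00692), with Tnfrsf17 at -2.81 ± 0.18. Their adjusted p with an estimated correlation was 0.367, 0.368, 0.28 and 0.28 in this order. Cell cycle genes rose in 11 of 12 (11 adjusted over the list alone, median 2.67, adjusted p = 5.92e-06, or 0.28 with an estimated correlation). Red pulp genes fell in 6 of 7, with haptoglobin, Hp, higher (6 and 1 adjusted over the list alone, adjusted p = 0.00133, or 0.28 with an estimated correlation). Classical activation genes fell in 14 of 23 and rose in 4 (14 and 4 adjusted over the list alone, adjusted p = 0.00274, or 0.28 with an estimated correlation). The chemokine Cxcl10 was at -3.34 ± 0.52 and the co-stimulator Cd40 at -2.72 ± 0.18, whereas Cxcl2 (2.60), Cxcl1, whose pool signal was not well above background (adjusted p = 1.95e-05), Tnf (0.98 ± 0.17) and Il12a (0.69) were higher. Pattern recognition receptors fell in 8 of 16 and rose in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.0278, or 0.28 with an estimated correlation), with Tlr6 and Cd14 higher, the latter at 1.59 ± 0.29 with Cy5 saturated on 1 of 2 arrays. Megakaryocyte and platelet markers did not pass at 18 weeks (2 of 6 higher, 2 adjusted over the list alone, adjusted p = 0.158, or 0.564 with an estimated correlation).

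Pattern recognition and scavenger receptors lost the call without 18 weeks replicate 2 (adjusted p = 0.119). Gbp3 and Iigp1 lost the call without 18 weeks replicate 1 (adjusted p = 0.0889 and 0.088). Both 18 week arrays lay on a slide and scan of their own, so slide and time cannot be told apart there.

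**Figure D3:**
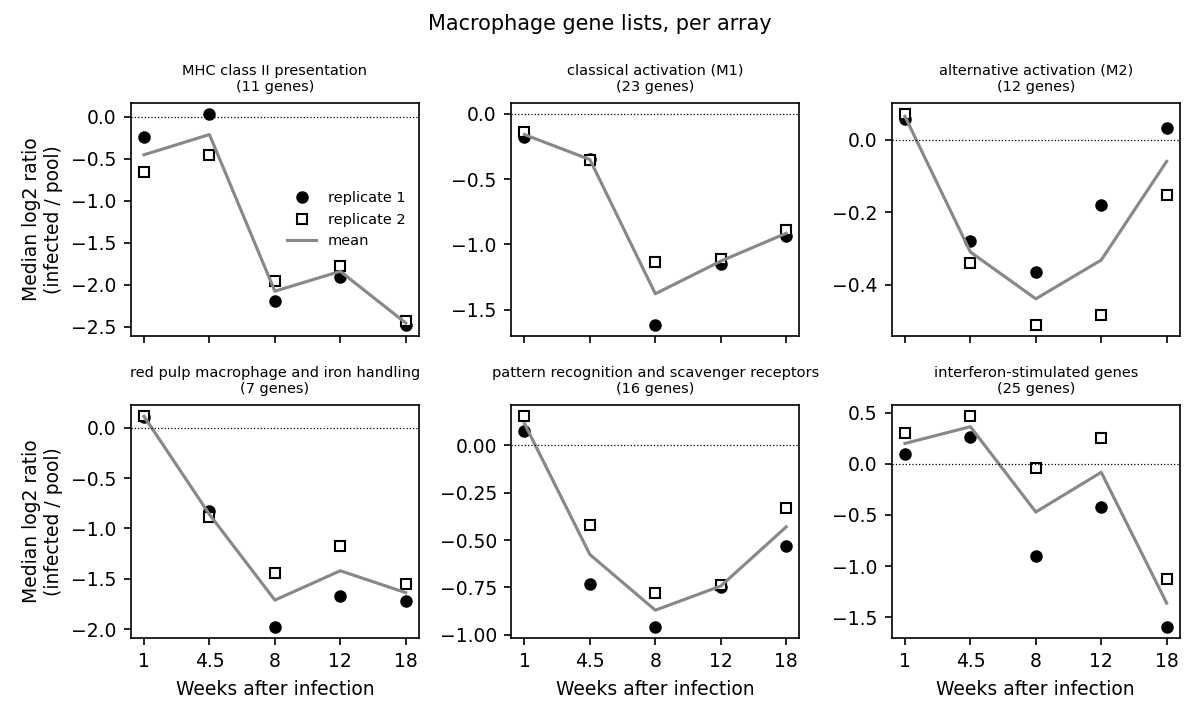
Median log2 ratio to the pool over the tested members of 6 gene lists (vertical axes) at each time (horizontal axes, weeks after infection). A filled circle marks replicate 1, an open square replicate 2 and a line their mean. The MHC class II medians lie at -2.20 and -1.96 on the 8 week arrays, and the interferon-stimulated medians at -0.90 and -0.04 there and at -1.60 and -1.13 on the 18 week arrays.

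Of 25 lists tested against the pool, 8 shifted at no time. Their lowest adjusted p over the 5 times was 0.065 for regulatory cytokines and checkpoints, 0.0844 for matrix and fibrosis, 0.142 for type 2 cytokines and receptors, 0.156 for basophil and mast cell markers, 0.168 for endothelial and stromal markers, 0.18 for glycolysis, 0.285 for erythroid markers and 0.72 for eosinophil markers. The eosinophil list held opposite changes. At 8 weeks the granule proteins Prg2 (2.95 ± 0.11) and Epx (2.62 ± 0.10) rose while the surface receptors Ccr3 (-3.36 ± 0.19) and Il5ra (-1.09 ± 0.14) fell. Spp1, the gene of osteopontin in the matrix list, rose by 2.97 ± 0.31 at 8 weeks and 2.57 ± 0.31 at 18 weeks, and Tgfb1 fell to -1.13 ± 0.06 at 12 weeks. A list of immediate early and heat shock genes had 2 measured members and was not tested.

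Of 21 genes fixed for display whatever their values, 13 were tested here. In order of time, Tnf stood at 0.04, 0.16, 1.38, 0.82 and 0.98 and Itgam at 0.53, 0.33, 2.02, 1.55 and 1.95, both past the test from 8 weeks on. Ifng stood at -1.62, 0.11, -2.32, -1.98 and -2.08, past the test at all times but 4.5 weeks, and Epx at 0.09, 2.62, 0.99 and 2.16 from 4.5 weeks on, past it from 8 weeks. The pool signal of Epx was well above background on 1 of 2 arrays at 4.5 and 12 weeks and on neither at 1 week, where it did not pass and has no measured ratio. Cd3e stood at -0.02, 0.91, -1.10, -0.40 and -0.72, higher at 4.5 weeks and lower at 8 and 18 weeks. The macrophage receptors Csf1r (-1.57, -1.31 and -1.94) and Adgre1, the gene of F4/80 (-1.71, -1.72 and -2.03), were lower at 8, 12 and 18 weeks and had saturated Cy5 before that. Csf1r was also past the test at 4.5 weeks (adjusted p = 0.0431), and Adgre1 there with the replicate block only (adjusted p = 0.0466). At 12 weeks Cy5 of Adgre1 was saturated on 1 of the 2 arrays. Il12b, a subunit of interleukin 12, was at least 2.12-fold lower at 8 weeks, when infected cells were not well above background, and also lower at 12 and 18 weeks, where this held for the probe used (adjusted p = 6.09e-05 and 7.41e-05). It stood at -0.30 at 4.5 weeks and at -0.25 at 1 week, where it did not pass. Chil3 was lower with saturated Cy5 at 1 and 4.5 weeks (adjusted p = 0.00479 and 0.00321) and at least 2.88-fold, at least 2.71-fold and at least 5.71-fold higher at 8, 12 and 18 weeks with saturated Cy5. Il1b was at least 3.12-fold lower at 8 weeks, with Cy3 saturated, and lower with saturated Cy5 at the other times. H2-Ab1 was called lower with saturated Cy5 at every time, but its dimmer unsaturated probe read -0.25 at 1 week. Il10 had a pool well above background on 1 array of 1 week, 1 of 12 weeks and no other, so that its ratio was not measured. It passed at no time (adjusted p from 0.0544 to 0.878), and at 18 weeks with the replicate block. At 1 week Chil3 lost the call without either array of 1 week (adjusted p up to 0.0953). Ifng did so without either array of 1, 4.5 or 8 weeks (up to 0.289). Il1b and H2-Ab1 did so without 1 week replicate 2 (0.103 and 0.0906). At 4.5 weeks Chil3 and Cd3e lost the call without 4.5 weeks replicate 1 (adjusted p = 0.0512 and 0.0616). Csf1r did so without either array of 1, 4.5 or 8 weeks (up to 0.343). Il12b did so without either array of 4.5 weeks (up to 0.221). At 12 weeks Tnf lost the call without 12 weeks replicate 2 (adjusted p = 0.0742). At 18 weeks Cd3e lost the call without 18 weeks replicate 1 (adjusted p = 0.0705).

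**Figure D4:**
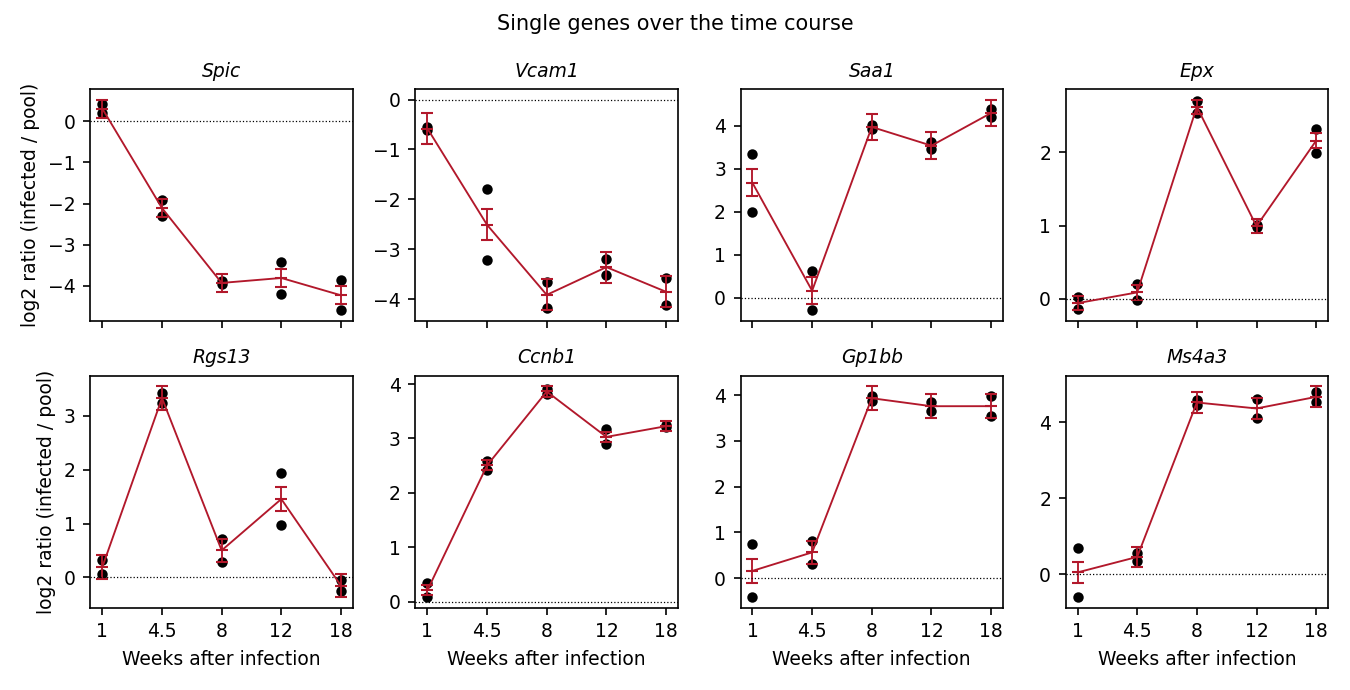
Log2 ratio of infected cells to the control pool (vertical axes) for 8 genes at each time (horizontal axes, weeks after infection), with black points for the 2 arrays and red lines and bars for the mean and its standard error. Rgs13 stands at 3.33 at 4.5 weeks, Saa1 at 2.67 at 1 week and 3.98 at 8 weeks, and Spic at -2.11 at 4.5 weeks and -4.23 at 18 weeks.

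Successive times were compared, where a dye or pool effect common to all arrays cancels but an age effect does not. The list test fry, which asks whether a list moves at all, kept 22 of the 44 list calls between times given below, 5 of 11 between 1 and 4.5 weeks, 13 of 14 between 4.5 and 8, 3 of 12 between 8 and 12, and 1 of 7 between 12 and 18 weeks. Between 1 and 4.5 weeks 253 genes differed (126 higher and 127 lower at 4.5 weeks). Rassf6 (3.18 ± 0.33, with the pool well above background on 1 of 2 arrays at 1 week), Rgs13 (3.14 ± 0.30), Nek2 (2.57 ± 0.24) and Cpne5 (2.32 ± 0.18) were higher at 4.5 weeks. Ccr3 (-3.31 ± 0.27), Saa3 (-2.65 ± 0.50), Saa1 (-2.51 ± 0.44) and C2 (-2.40 ± 0.17) were lower. Spic, saturated in Cy5 at 1 week, was also lower (adjusted p = 0.00959). Cell cycle genes moved up (8 of 12, 10 adjusted over the list alone, adjusted p = 7.9e-10, or 0.347 with an estimated correlation), as did B cell markers (2 of 12, 3 adjusted over the list alone, adjusted p = 0.00227, or 0.453 with an estimated correlation). T cell markers moved up as a list (adjusted p = 1.99e-07, or 0.365 with an estimated correlation) with 0 of 13 past the test over all genes and 10 adjusted over the list alone. NK markers did likewise with 0 and 5 of 10 (adjusted p = 0.000467, or 0.401 with an estimated correlation). Pattern recognition receptors moved down (3 of 16, 7 adjusted over the list alone, adjusted p = 3.67e-09, or 0.136 with an estimated correlation), with red pulp genes (3 of 7, 4 adjusted over the list alone, adjusted p = 9.37e-06, or 0.347 with an estimated correlation).

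With the replicate block 450 genes differed between 1 and 4.5 weeks, with scaling between arrays 879, and without 1 array of these times 91 or 86 (1 week replicate 1 or 2) and 71 or 74 (4.5 weeks replicate 1 or 2), or 148 without either array of 8 weeks. Monocyte and macrophage identity (1 of 14, 2 adjusted over the list alone), alternative activation (2 of 12, 2 adjusted over the list alone), complement (2 of 19, 3 adjusted over the list alone) and matrix lists (1 of 4, 2 adjusted over the list alone) also moved down, at an adjusted p of 0.00227, 0.0261, 0.0335 and 0.0335, or 0.347, 0.347, 0.365 and 0.347 with an estimated correlation. Plasma cell markers (1 of 7, 1 adjusted over the list alone) moved up, with an adjusted p of 0.0303, or 0.365 with an estimated correlation and 0.067 without saturated spots, where complement had 0.266 and neither passed. Alternative activation (M2) and plasma cell markers lost the call without 4.5 weeks replicate 1 (adjusted p = 0.0645 and 0.0649). B cell markers and matrix and fibrosis did so without 1 week replicate 2 or 4.5 weeks replicate 1 (up to 0.201 and 0.0743). Monocyte and macrophage identity did so without 1 week replicate 1 (0.0587). Complement and Fc receptors did so without 1 week replicate 1 or 4.5 weeks replicate 2 (up to 0.211). Saa1 did so without either array of 4.5 or 8 weeks or 1 week replicate 1 (up to 0.166). Saa3 did so without either array of 4.5, 8, 12 or 18 weeks or 1 week replicate 1 (up to 0.191). Spic did so without either array of 1 or 4.5 weeks (up to 0.0821).

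Between 4.5 and 8 weeks 1764 genes differed, 873 higher and 891 lower at 8 weeks. Saa1 rose by 3.81 ± 0.44. Ctsg, Ms4a3 and Mpo, saturated in Cy5 at 8 weeks, also rose (adjusted p = 0.000535, 0.000802 and 0.000535), as did Slc4a4, whose pool signal was not well above background (adjusted p = 0.000535). Tnfrsf13c (-3.49 ± 0.36), Rassf6 (-3.19 ± 0.33), the T cell receptor gene Tcrb (-3.17 ± 0.30) and Slamf8 (-3.11 ± 0.89, with Cy5 saturated on 1 of 2 arrays at 4.5 weeks) fell. So did the chemokine receptor Cxcr6, which was not well above background at 8 weeks (adjusted p = 0.00629). T cell markers fell in 12 of 13 (12 adjusted over the list alone, adjusted p = 3.37e-09), B cell markers in 11 of 12 (11 adjusted over the list alone, adjusted p = 4.15e-08), NK markers in 8 of 10 with Gzmk higher (8 and 1 adjusted over the list alone, adjusted p = 8.96e-05) and MHC class II genes in 8 of 11 (8 adjusted over the list alone, adjusted p = 1.01e-06). The adjusted p with an estimated correlation was 0.347, 0.347, 0.39 and 0.347 in this order. Cell cycle genes rose in 9 of 12 (11 adjusted over the list alone, adjusted p = 4.44e-05, or 0.347 with an estimated correlation) and neutrophil markers in 4 of 5 (4 adjusted over the list alone, adjusted p = 0.00139, or 0.347 with an estimated correlation). Without saturated spots 3 neutrophil markers were left, 1 of them higher, and the list was not tested.

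Interferon-stimulated genes were also lower at 8 than at 4.5 weeks (5 of 25, 5 adjusted over the list alone, adjusted p = 0.000165), with classical activation (10 of 23, 11 adjusted over the list alone beside 1 higher, namely Tnf, adjusted p = 0.000165), dendritic cell (4 of 6, 4 adjusted over the list alone, adjusted p = 0.0008), red pulp (3 of 7, 4 adjusted over the list alone beside 1 higher, namely Hp, adjusted p = 0.0231) and regulatory genes (5 of 11, 6 adjusted over the list alone beside 1 higher, namely Ebi3, adjusted p = 0.0444). With an estimated correlation the adjusted p was 0.497, 0.347, 0.347, 0.39 and 0.347 in this order. Plasma cell genes were lower (4 of 7, 4 adjusted over the list alone beside 1 higher, namely Edem1, adjusted p = 0.04, or 0.366 with an estimated correlation, 0.102 with the replicate block and 0.0955 without saturated spots). Glycolysis (3 of 4, 3 adjusted over the list alone, adjusted p = 0.025, or 0.347 with an estimated correlation and 0.141 without saturated spots) and platelet genes (2 of 6, 2 adjusted over the list alone, adjusted p = 0.0303, or 0.451 with an estimated correlation) were higher. Erythroid markers passed with the replicate block only (adjusted p = 0.0444). Without 4.5 weeks replicate 1 or 2, 875 or 1007 genes differed, and without 8 weeks replicate 1 or 2, 851 or 952. Plasma cell markers lost the call without 4.5 weeks replicate 1, 8 weeks replicate 2 or 12 weeks replicate 2 (adjusted p up to 0.0743). Megakaryocyte and platelet markers did so without 4.5 weeks replicate 1 or 8 weeks replicate 2 (up to 0.138). Regulatory cytokines and checkpoints did so without either array of 1 or 12 weeks, 4.5 weeks replicate 1 or 8 weeks replicate 1 (up to 0.0877). Slamf8 did so without either array of 1, 4.5, 8 or 18 weeks (up to 0.212).

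Between 8 and 12 weeks 1 gene differed. Epx, the eosinophil peroxidase, was lower at 12 weeks, with a log2 difference of -1.63 ± 0.14 (adjusted p = 0.0443) and a pool well above background on only 1 of the 2 arrays of 12 weeks, and 637 genes had an unadjusted p under 0.05 in limma. With the replicate block 2 genes passed. As lists, T cell (3.71e-09), B cell (0.000258), MHC class II (0.000843), classical activation (0.00382), interferon-stimulated (0.00753), type 2 (0.0252), pattern recognition (0.0275) and NK cell genes (0.0303) moved up at the adjusted p given, and cell cycle (4.07e-05), eosinophil (0.0165), matrix (0.0197, or 0.0983 with the replicate block) and erythroid genes (0.0261) moved down. With an estimated correlation these adjusted p lay between 0.347 for T cell and 0.592 for interferon-stimulated genes. Apart from Epx no member of these lists passed over all genes tested. Adjusted over the list alone, 3 T cell genes rose, 1 type 2 gene rose, 4 cell cycle and 2 matrix genes fell, and 2 eosinophil genes fell beside 1 higher. Plasma cell markers passed with the replicate block only (0.0472).

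The call of Epx between 8 and 12 weeks ended without either array of 1, 4.5, 8 or 12 weeks (adjusted p up to 0.795), and it was absent with Agilent's processed signals, scaling between arrays, the stricter filter and the trended robust fit, each with 0 genes. NK cell and cytotoxic markers, classical activation (M1) and interferon-stimulated genes lost the call without 8 weeks replicate 1 or 12 weeks replicate 2 (adjusted p up to 0.6, 0.243 and 0.87). B cell markers and matrix and fibrosis lost the call without 12 weeks replicate 2 (adjusted p = 0.0802 and 0.168). Pattern recognition and scavenger receptors, erythroid markers and type 2 cytokines and receptors lost the call without either array of 12 weeks or 8 weeks replicate 1 (adjusted p up to 0.351, 0.155 and 0.0885). Eosinophil markers lost the call without either array of 4.5 weeks or 12 weeks replicate 2 (adjusted p up to 0.163). Without saturated spots the adjusted p was 0.067 for MHC class II and 0.112 for NK genes.

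Between 12 and 18 weeks 33 genes differed, 18 higher and 15 lower at 18 weeks. Plk3 (2.93 ± 0.26), the prion protein gene Prnp (2.71 ± 0.35), Rgs1 (2.55 ± 0.24) and Nfkbiz (1.57 ± 0.19) were higher at 18 weeks, and so was Fn1, the gene of fibronectin, with Cy5 saturated at 18 weeks (adjusted p = 0.0421). Tnfrsf13c (-2.51 ± 0.36), Bfsp2 (-1.48 ± 0.17), Ttc7 (-1.39 ± 0.13, with Cy5 saturated on 1 of 2 arrays at 12 weeks), Aagab (-1.35 ± 0.18) and Mvk, a kinase of the mevalonate pathway (-1.20 ± 0.15), were lower. Interferon-stimulated genes moved down with a median of -1.03 (adjusted p = 8.88e-07, or 0.404 with an estimated correlation, 0 of 25 past the test over all genes and 0 adjusted over the list alone), with B cell (2.18e-05, 0 and 6 of 12), T cell (6.4e-05, 0 and 6 of 13), MHC class II (0.00087, 0 and 4 of 11), plasma cell (0.0165, 0 and 3 of 7) and erythroid markers (0.000954, 1 and 2 of 11). Under an estimated correlation these adjusted p were 0.404, 0.365, 0.418, 0.365, 0.347 and 0.365. Eosinophil markers moved up (adjusted p = 0.045, or 0.401 with an estimated correlation and 0.0766 with the replicate block, with 2 of 4 members, and 2 adjusted over the list alone).

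The count between 12 and 18 weeks was 137 with the replicate block (52 higher, 85 lower), 40 with median centring (26 higher, 14 lower), 21 with the stricter filter or the trended robust fit, 19 with the series matrix values, 3 with array weights and 1 with scaling. Leaving out 1 array gave 4 without either array of 1 week, 5 without either of 4.5 weeks, 1 without either of 8 weeks, 148 (38 higher, 110 lower) or 2 without 12 weeks replicate 1 or 2, and 6 or 111 without 18 weeks replicate 1 or 2. Plasma cell markers lost the call without 12 weeks replicate 1 or 18 weeks replicate 1 (adjusted p up to 0.161). Eosinophil markers lost the call without either array of 4.5 or 8 weeks, 12 weeks replicate 2 or 18 weeks replicate 2 (adjusted p up to 0.16). Aagab, Bfsp2, Mvk, Prnp and Tnfrsf13c lost the call without either array of 1, 4.5 or 8 weeks, 12 weeks replicate 2 or 18 weeks replicate 1 (adjusted p up to 0.182, 0.111, 0.123, 0.179 and 0.172). Fn1 lost the call without either array of 1, 4.5, 8 or 18 weeks (adjusted p up to 0.122). Nfkbiz lost the call without either array of 1 or 8 weeks, 12 weeks replicate 2 or 18 weeks replicate 1 (adjusted p up to 0.149). Plk3 lost the call without either array of 8 weeks or 12 weeks replicate 2 (adjusted p up to 0.0938). Rgs1 lost the call without either array of 1, 4.5 or 8 weeks or 12 weeks replicate 2 (adjusted p up to 0.0938). Ttc7 lost the call without either array of 8 weeks, 12 weeks replicate 2 or 18 weeks replicate 1 (adjusted p up to 0.0938). Without saturated spots the adjusted p of MHC class II was 0.0529. Slide and time cannot be told apart in this comparison.

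Over all 5 times together 2560 genes changed (limma F-test, adjusted p under 0.05), and 1631 did without 1 week replicate 1. In simulated arrays with the measured spread, changes of 1.5, 2 and 4-fold at 8 weeks were recovered in 74.6%, 92.5% and 100% of cases against the pool, with 12 false calls among 199 calls, and in 31.3%, 83.6% and 95.5% between 8 and 12 weeks.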

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

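Both tests of saturation at 1 week, the test of a lower share of the main cell type and the test without saturated spots at 8 weeks were chosen only after the result was seen.

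At 1 week 304 of 478 changed genes were lower, and 135 of these had Cy5 saturated on both arrays (132 once names that differ only in letter case are joined). Without saturated spots 187 genes changed, below the 342 unsaturated calls, so this decides nothing. Dimmer unsaturated probes of 31 saturated genes (14 below 0) had a median log2 ratio of 0.0196 against -0.827 for the saturated probes. Saturation may account for these lower values. For a dye or pool effect that is the same on every array, a bound written beforehand asked for under 75% of the unsaturated changed genes to keep their sign at 18 weeks if it were not the cause, and 67.4% of 342 did (81.3% at 4.5, 73.9% at 8 and 67.8% at 12 weeks). That bound was met, but set aside as undecided only after this value was seen. The SD of all log2 ratios was 0.754 at 18 weeks and 0.279 at 1 week, so later changes could override a small constant effect. For these 31 genes the quartiles of the dimmer probes (-0.194 and 0.243) speak against a fall as deep as -0.827. For saturated genes without such a probe a true fall stays open.

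At 8 weeks T, B and NK cell markers were lower and cell cycle and platelet markers higher than in the pool (adjusted p = 5.92e-06, 5.92e-06, 0.000906, 4.15e-06 and 0.0051 in this order, or 0.351, 0.328, 0.368, 0.28 and 0.347 with an estimated correlation). At 8 weeks the highest lymphocyte list median on any array was -1.40 and the lowest neutrophil or platelet median 1.16. A lower share of the main cell type alone would raise both, but the gap (2.56) only restates the pattern. Saturation does not account for the list calls, as 5 of 5 (T, B and NK cell, cell cycle, platelet) were left without saturated spots, but none was left with an estimated correlation. Myeloid progenitors could carry Ms4a3, Ctsg and Mpo, although beads would miss those with little CD11b. Their 5 other measured markers (2 higher, 1 lower) had a median of 0.22, which leaves this open. Nkg7 is also an NK and Kit a mast cell marker. A change in the cells held by the beads and a change within cells over the infection stay open as biological explanations, untested here. A pool difference between arrays also stays open.

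Interferon-stimulated genes were lower at 18 than at 12 weeks with a median of -1.03 (adjusted p = 8.88e-07, or 0.404 with an estimated correlation and 0.119 with fry), while 7235 other genes had a median of -0.0284. With the replicate block the list had an adjusted p of 8.82e-09, or 0.475 with an estimated correlation as well, but this decides nothing about a difference between the replicates at every time, because each time holds both and such a difference cancels between times. Slide and time cannot be told apart for this list, because the slide of 18 weeks holds no other time. Effects of time since infection, of age and of that slide therefore stay open.

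The results below stood out because all arrays of 1 time lay above 0 and all of the next below it, or the reverse, with a tested difference. Between 1 and 4.5 weeks the list medians of the difference were alternative activation (-0.20), red pulp (-0.89), pattern recognition (-0.68), matrix (-0.29) and T cell markers (1.00). The adjusted p was 0.0261, 9.37e-06, 3.67e-09, 0.0335 and 1.99e-07 in this order, and 0.347, 0.347, 0.136, 0.347 and 0.365 with an estimated correlation, and fry gave 0.0612 for alternative activation and 0.0545 for T cell markers. Single genes were Ccr3 (-3.31), Nr1h3 (-1.40), Stab2 (-2.07), Tslp (-1.02) and Prg2 (1.63). Of the calls against the pool these rest on, at 1 week Ccr3 lost the call without either array of 1 week (adjusted p up to 0.207). Nr1h3 did so without 1 week replicate 1 (0.152). Stab2 did so without either array of 1 or 8 weeks (up to 0.223). Tslp did so without either array of 1, 4.5, 8 or 18 weeks (up to 0.367). Prg2 did so without either array of 1, 4.5 or 8 weeks (up to 0.26). At 4.5 weeks Tslp lost the call without 4.5 weeks replicate 2 (adjusted p = 0.0865). Between 1 and 4.5 weeks the call of 2 lists was lost. Alternative activation (M2) lost the call without 4.5 weeks replicate 1 (adjusted p = 0.0645). Matrix and fibrosis lost the call without 1 week replicate 2 or 4.5 weeks replicate 1 (adjusted p up to 0.0743). Between 4.5 and 8 weeks the list medians were interferon-stimulated genes (-0.97), neutrophil (2.27), plasma cell (-0.60) and T cell markers (-2.32). The adjusted p was 0.000165, 0.00139, 0.04 and 3.37e-09 in this order, and 0.497, 0.347, 0.366 and 0.347 with an estimated correlation, and interferon-stimulated genes had 0.117 with fry. Plasma cell markers did not pass with the replicate block (0.102) or without saturated spots (0.0955), where neutrophil markers were not tested. Plasma cell markers lost the call without 4.5 weeks replicate 1, 8 weeks replicate 2 or 12 weeks replicate 2 (adjusted p up to 0.0743).

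Between 4.5 and 8 weeks the T cell genes Cd3g (-2.96), Cd8b1 (-3.03), Lat (-2.70), Cd3d (-2.56), Tbx21 (-2.50), Cd8a (-2.16), Cd6 (-2.69), Cd28 (-2.41), Cxcr6 (adjusted p = 0.00629), Tcrb (-3.17) and Cd3e (-2.02) crossed 0, with Cxcr6 not well above background at 8 weeks. The other probes of Cd8b1 disagreed at 8 weeks. Genes of B cells or others were Cd22 (-2.75), Cd72 (-2.51), Tnfrsf13c (-3.49), Bfsp2 (-2.61), Ctla4 (-1.70) and Ccl24 (0.87). Fpr1 crossed upward (adjusted p = 0.000549), with Cy5 saturated at 8 weeks. So did Chil3 and C3 (0.000535 and 0.000802), but with Cy5 saturated at both times, so no rise in Cy5 was measured. Of the 4.5 week calls, Cd3g, Cd8b1, Cd8a, Cd3e and Chil3 lost the call without 4.5 weeks replicate 1 (adjusted p = 0.11, 0.141, 0.0883, 0.0616 and 0.0512). Lat, Cd3d, Tbx21, Cd22, Cd72, Ctla4 and Ccl24 lost the call without either array of 4.5 weeks (adjusted p up to 0.154, 0.135, 0.219, 0.132, 0.146, 0.0647 and 0.0938).

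Between 8 and 12 weeks the list medians were type 2 cytokines and receptors (0.035) and eosinophil markers (-0.70), the former with a mean of 0.295. The adjusted p was 0.0252 and 0.0165 in this order, and 0.347 and 0.365 with an estimated correlation. Type 2 cytokines and receptors lost the call without either array of 12 weeks or 8 weeks replicate 1 (adjusted p up to 0.0885). Eosinophil markers lost the call without either array of 4.5 weeks or 12 weeks replicate 2 (adjusted p up to 0.163). Between 12 and 18 weeks the eosinophil markers had 0.54, with an adjusted p of 0.045, or 0.401 with an estimated correlation and 0.0766 with the replicate block. Genes that crossed 0 there were Plk3 (2.93), Ctla4 (0.98), Fn1 (adjusted p = 0.0421), Nfkbiz (1.57), Aagab (-1.35) and Mvk (-1.20), with Cy5 of Fn1 saturated at 18 weeks. For the difference between 12 and 18 weeks the call was lost as follows. Eosinophil markers lost the call without either array of 4.5 or 8 weeks, 12 weeks replicate 2 or 18 weeks replicate 2 (adjusted p up to 0.16). Plk3 lost the call without either array of 8 weeks or 12 weeks replicate 2 (adjusted p up to 0.0938). Fn1 lost the call without either array of 1, 4.5, 8 or 18 weeks (adjusted p up to 0.122). Nfkbiz lost the call without either array of 1 or 8 weeks, 12 weeks replicate 2 or 18 weeks replicate 1 (adjusted p up to 0.149). Aagab and Mvk lost the call without either array of 1, 4.5 or 8 weeks, 12 weeks replicate 2 or 18 weeks replicate 1 (adjusted p up to 0.182 and 0.123).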

How the results depend on the processing

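The tests without saturated spots, with the series values as given, with names joined across letter case and with the replicate block together with an estimated correlation were chosen only after the results were seen.

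Of 481 named gene calls 324 kept direction and threshold under every alternative that tested them, other than the 2-fold minimum, and 157 did not. Of 98 list calls 57 did so, leaving out an estimated correlation and fry, and 41 did not. Over all alternatives gene results kept their call and direction in 11580 cases, lost the call in 668, gained one in 17, changed sign without a call in 16 and changed sign from a call in 7. For lists these numbers were 5375, 378, 107, 154 and 2. Where no cause is given below, the cause was not tested.

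A 2-fold minimum left 64 genes at 1 week, 216 at 4.5, 925 at 8, 807 at 12 and 977 at 18 weeks, and 132, 743 and 18 between 1 and 4.5, 4.5 and 8, and 12 and 18 weeks. Median centring gave 1843 genes and 2 lists at 1 week and 2863 genes at 4.5 weeks. Scaling between arrays gave 1975 and 2173 genes at these times, 879 between them, 0 between 8 and 12 weeks, where 637 had an unadjusted p under 0.05 in the limma fit, and 1 between 12 and 18 weeks. Median centring put the median of all genes at 0.13, 0.122 and 0.111 at 8, 12 and 18 weeks and at 0.106 between 4.5 and 8 weeks. The split of higher and lower genes moved to 135 and 516 at 1 week and 560 and 1030 at 4.5 weeks with Agilent's processed signals, to 871 and 972 at 1 week and 26 and 14 between 12 and 18 weeks with median centring, to 992 and 983, and 1 and 0, with scaling, and to 16 and 3 between 12 and 18 weeks with the series values. With a 2-fold minimum it moved to 6 and 58 at 1 week, 359 and 566 at 8, 298 and 509 at 12 and 304 and 673 at 18 weeks, and without saturated spots to 93 and 94 at 1 week and 15 and 8 between 12 and 18 weeks, where the replicate block gave 52 and 85 and array weights 3 and 0.

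Between 8 and 12 weeks Agilent's processed signals gave 0 genes, the stricter filter 0, the trended robust prior 0 and the series values 2. Between 12 and 18 weeks the stricter filter gave 21, the trended robust prior 21, the series values 19 and array weights 3. At 1 week array weights gave 747 genes, and the stricter filter, which tests fewer genes, 2 lists. Joining names across letter case gave 474, 1315, 3902, 3676 and 3879 genes at the 5 times and 254, 1754, 1 and 33 between times, and changed no named gene or list call. Without saturated spots 187 genes and 1 list passed at 1 week and 6 lists at 4.5 weeks. The series values as given, with values out of place, gave 0, 0, 223, 1 and 222 genes against the pool, 0, 33, 45 and 8 between times and 30 over all times, with 77 higher and 146 lower at 8, 1 and 0 at 12, 70 and 152 at 18, and 24 and 21 between 8 and 12 weeks.

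With the replicate block 784 genes passed at 1 week, 1995 at 4.5 weeks, 450 between 1 and 4.5 weeks, 2 between 8 and 12 weeks and 137 between 12 and 18 weeks. It changed 3 of 501 named gene results, Cd8b1 at 12 weeks lost and Il10 at 18 weeks and Adgre1 at 4.5 weeks gained, and 10 of 225 list results, and no other call. With an estimated correlation 0 lists passed at each time and 0 between times, with or without the replicate block, where the lowest adjusted p was 0.253 against the pool and 0.136 between times without it. The test fry, which asks whether a list moves and not whether it moves more than other genes, gave 10 lists at 1 week, 17 at 4.5, 22 at 8, 21 at 12 and 23 at 18 weeks and 31 between times. It kept 53 of 54 list calls against the pool, all but interferon-stimulated genes at 8 weeks (0.1), but 22 of 44 between times. Among those lost between 1 and 4.5 weeks were T cell (0.0545), NK cell (0.0936) and B cell markers (0.146).

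Leaving out 1 array, where a lone array is assumed to vary like the other times, gave 64 to 523 genes at 1 week, 340 to 1407 at 4.5 weeks, 2223 to 3936 at 8 weeks, 2155 to 3735 at 12 weeks and 2490 to 3862 at 18 weeks. Between times it gave 71 to 296, 851 to 1819, 0 to 1 and 1 to 148 genes in order, and 1631 to 2545 over all times. The lowest of these lacked an array of a time compared, other than between 12 and 18 weeks, where the lowest lacked either array of 8 weeks, and between 8 and 12 weeks, where 0 genes passed without any 1 of the 8 arrays of 1 to 12 weeks. The split moved to 7 higher and 99 lower at 1 week without 1 week replicate 1, to 13 and 51 without replicate 2, and to 28 and 43 between 1 and 4.5 weeks without 4.5 weeks replicate 1. Between 12 and 18 weeks it moved to 38 and 110 without 12 weeks replicate 1, 2 and 0 without 12 weeks replicate 2, 6 and 0 without 18 weeks replicate 1, and 1 and 0 without either array of 8 weeks. Lists numbered 3 to 8, 10 to 11, 12 to 15, 13 to 14 and 10 to 12 at the 5 times and 32 to 47 between times, with 8 at 1 week without 1 week replicate 1.

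Reversed at 1 week were Irf1, at 0.024 with the mean of all probes and 0.31 without saturated spots, Ctsb, at 0.33 with the series values and 0.32 without saturated spots, and Ifi30, at 0.37 without saturated spots. Reversed at 4.5 weeks were Ifi30, at 0.28 without saturated spots, and Ighm, at 0.0015 with the series values. The MHC class II list at 4.5 weeks turned upward without saturated spots (adjusted p = 0.96), and the list interferon-stimulated genes between 12 weeks and 8 weeks turned downward without 8 weeks replicate 1 (adjusted p = 0.414), lost the call without 12 weeks replicate 2 (0.87) and had an adjusted p of 1.92e-10 without 8 weeks replicate 2. Of the genes lower at 1 and 4.5 weeks 44.4% and 20.7% had Cy5 saturated on both arrays, and 400 genes higher at 8 weeks had a pool not well above background and have only a bound.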

Other observations

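No test in this part was chosen only after its result was seen, but the genes of this and the next paragraph, and the 3 genes that led to the test of germinal centre markers, were picked after their values were seen. The eosinophil granule gene Prg2 and the eosinophil receptor gene Ccr3 had opposite signs at every time. Prg2, the major basic protein, stood in order of time at -0.59, 1.04, 2.95, 1.63 and 3.05 and passed the test at each time, and it was higher at 4.5 than at 1 week by 1.63. Epx, the peroxidase of the same granules, passed from 8 weeks on. Ccr3 stood at 1.16, -2.15, -3.36, -2.61 and -3.22 and passed at each time, and Il5ra, the receptor for interleukin 5, at -0.19, -0.16, -1.09, -1.16 and -1.26, past the test from 8 weeks on. At 1 week Prg2 lost the call without either array of 1, 4.5 or 8 weeks (adjusted p up to 0.26). Ccr3 lost the call without either array of 1 week (adjusted p up to 0.207).

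Serum amyloid A genes passed the test at 1 week, and orosomucoid genes from 8 weeks on. Orm1 stood at 3.80, 3.73 and 4.59 from 8 weeks, and Orm2 in order of time at 0.24, 0.45, 3.69, 3.36 and 4.15. The control signal of Orm1 was well above background on neither array of 1 week and on 1 of 2 at 4.5 weeks, so that its earlier values are not given. Saa3 stood at 2.49 at 1 week and -0.16 at 4.5 weeks, where it did not pass, and was higher with saturated Cy5 at 8 and 18 weeks. Saa1 at 4.5 weeks was 0.16 and did not pass. Saa3 lost the call without 1 week replicate 1 (adjusted p = 0.0986). Whether the time of the rise differed between these families was not tested.

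Rgs13, Rassf6 and Ackr4 were higher at 4.5 weeks. Rgs13 may come from germinal centre B cells, which CD11b beads should mostly remove, yet 3 of 12 B cell markers had saturated Cy5 there. Of markers listed before the test, 4 besides Rgs13 were measured. Their median log2 ratio at 4.5 weeks was 0.978, above the 0.5 asked for beforehand. S1pr2 (1.65 ± 0.13) and Neil1 (1.90 ± 0.17) were higher, while Fas (0.31 ± 0.16) and Tnfrsf17 (-0.19 ± 0.18), the latter also in the plasma cell list, did not pass. The broader B cell list did not pass at 4.5 weeks (median 0.23, adjusted p = 0.12). A change of these genes in other cells stays open, and with 4 markers the result is a hypothesis only.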
